A study of Homo sapiens with 9 samples.

How the data were processed

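Gene expression was measured in LiSa-2 cells, a human liposarcoma cell line, with Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array per sample and 9 arrays in all. Per the labels, cells grown on plates received bovine testicular hyaluronidase (HAase), an enzyme that cleaves hyaluronan, at 400 µg/mL, or phosphate-buffered saline (PBS), and total RNA was extracted with a column kit. There were 3 groups of 3 samples: PBS, HAase for 6 h and HAase for 24 h. The PBS samples were all taken at 24 h, per the series design text.

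The deposited values are linear signal intensity per probe set, made by the authors from Affymetrix CHP files, per the series design text. The summarisation algorithm, its version and any filter are not given in the sources used here. The values themselves showed a scaling per array before deposit: the mean after trimming 2% at each end lay between 500.07 and 500.075 on the 9 arrays. No value was negative or missing. The medians of the arrays lay between 55.83 and 61.31. The number of arrays limits the precision. The authors' own analysis used other files of the same arrays, per the same text, and was not used here.

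The table held 54675 probe sets, of which 62 were controls. Of the others, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none there, which leaves them unnamed here. The gene IDs of 41037 of the probe sets with 1 symbol were found in a RefSeq gene table of assembly GRCh38.p14, and no symbol needed an update. No coordinates are given, because the array files name no genome build. Probe sets with several symbols or none were left out of the gene tests. They include probe sets of some genes of the fixed lists, which are not analysed here.

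Signals were used as log2(signal + 16) with no further normalization, so fold changes are on that scale and understate changes of dim genes. Each of 19775 genes was represented by its probe set of highest mean over the 9 arrays. Genes whose mean lay below the 30th percentile (a signal of about 32.2) were left out, and 13842 genes were tested. A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the 3 groups shared 1 estimate of the spread per gene. The 3 comparisons were 24 h HAase with PBS, 6 h HAase with PBS, and 24 h with 6 h HAase. All p-values given as adjusted are those of limma and its gene set tests, or of fgsea where preranked enrichment is named, with Benjamini-Hochberg adjustment within a comparison, and a gene was called changed at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) from this model.

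The labels do not say whether the samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. A permutation of 3 samples against 3 cannot give a two-sided p under 0.1, and chance alone separates the arrays of 10% of genes.

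A group whose 3 arrays all lay at or below the brightest of 27 control probe sets for Bacillus subtilis transcripts on the same array has only an upper bound. The fold change of such a gene is written "at least" and was computed against that control level, which reached 65. Where only some arrays of a group lay above their own control level, the fold change is the model's and its size is uncertain. The number of such arrays is given where the gene's main result is described, not where alternatives are listed.

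The 35 gene lists, fixed before the data were examined, cover signalling, metabolism, matrix, stress, the cell cycle and markers of adipocytes and of epithelial, leukocyte and endothelial cells. Each was tested with camera (preset inter-gene correlation 0.01), which compares its members with the other genes. The alternatives were camera with an estimated correlation, fry, and preranked gene set enrichment analysis with fgsea 1.28.0. Camera with an estimated correlation is also stricter in another way: its test rests on the few arrays rather than on the number of genes. A call lost with it thus need not mean that the members vary together. Lists share members: 22 of the 28 tested members of the list of mRNAs with AU-rich elements are also in another list. The cell type lists are small after the filter, with 7, 6 and 3 tested members for epithelial, leukocyte and endothelial cells.

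The genes named were set by a rule made before the data were examined. For each comparison with PBS these were the 10 largest rises and the 10 largest falls among genes past the test whose arrays did not overlap, and for the comparison of the times the 5 largest of each. Ranks follow the model's fold changes, so the place of a gene whose change is given as a bound is uncertain. TXNIP, ARRDC4, ZFP36, SLC2A1, SLC2A3, HK2, CD44, HAS2 and HAS3 were named in every comparison, and up to 4 members per list by size of change. Genes named outside this rule are said to have been chosen after their values were seen.

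The alternatives, also set before the data were examined, were the mean of all probe sets of a gene, each probe set on its own above the same dim level, no filter or a 50th percentile filter on dim genes, quantile normalization, equal array medians, offsets of 32 and 1, only the 6 arrays of the 2 groups, the replicate number as a block, a trended and robust variance model, the other set tests, and leaving out each array. The scripts were tested on simulated data with the real genes' means and spreads. In the simulation of 24 h HAase against PBS over 13842 genes, 0 of 50 genes changed by 0.25 (log2) were recovered, 21 of 50 changed by 0.5, 36 of 50 changed by 1 and 48 of 50 changed by 2, with 4 calls among the unchanged genes. For 6 h HAase against PBS, also over 13842 genes, the numbers were 0, 25, 43 and 48 of 50, with 6 such calls, and for 24 h against 6 h they were 1, 16, 43 and 48 of 50, also with 6. All 10 simulated lists shifted by 0.3 were recovered in each comparison, with 0, 1 and 0 calls among 30 unchanged lists. Far fewer genes changed in the simulations than were called in the real data, which makes the adjusted threshold stricter there. The shares recovered therefore do not carry over to the real comparisons. Simulated genes also varied independently, so the list calls do not measure false calls among correlated genes.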

Results

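Expression was compared in LiSa-2 liposarcoma cells given PBS or 400 µg/mL hyaluronidase for 6 h or 24 h, with 3 arrays per group. The title of the series names extracellular matrix remodeling, glucose metabolism and TXNIP, the thioredoxin-interacting protein that limits glucose uptake. Arrays of 1 group correlated more closely with each other (median r across genes between 0.9892 and 0.9907) than with any array of another group (at most 0.9736). The first principal component, with 51.5% of the variance, ran from PBS through 6 h to 24 h, and the second, with 23.1%, set the 6 h arrays apart from the others.

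After 24 h of hyaluronidase, inflammatory mediators and matrix proteases were prominent among the genes that rose most, and adipocyte genes among those that fell. CXCL8, a neutrophil chemokine, rose from a signal of 100.4 ± 11.1 to 25100 ± 1770 (SD, n = 3 each), a log2 fold change of 7.76 ± 0.08 (SE). The collagenase gene MMP1 rose at least 72.1-fold, from a level within the range of the control probe sets to 4663 ± 81.2 (SD, n = 3). The lipid droplet protein gene PLIN1 was 13.4-fold lower, and adiponectin (ADIPOQ), a hormone of fat cells, was 17.7-fold lower, to a level above the control probe sets on only 1 of the 3 arrays. HAS2, which makes hyaluronan, the substrate of the enzyme, rose 24.3-fold from 213.2 ± 27.3 to 5542 ± 513 (SD, n = 3 each).

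The question of this comparison is how the transcriptome after 24 h with the hyaluronidase preparation differs from PBS at a matched harvest time. By limma, 5577 of the 13842 genes tested changed (40.3%), 2423 higher and 3154 lower, of which 554 and 588 changed 2-fold or more. The 3 arrays of the groups did not overlap in 52.0% of the tested genes, against 10% by chance. The median log2 fold change of all genes was -0.026. By the model's fold change, the other largest rises were those of the cytokine gene IL24 (144-fold), the collagen-binding integrin gene ITGA2 (73.6-fold), CXCL3 (44.8-fold), the anti-apoptotic gene BCL2A1 (at least 22.1-fold), the stromelysin gene MMP3 (38.7-fold), CCL20 (at least 9.95-fold), DNER (31.2-fold) and IL1B (29.3-fold). The places of BCL2A1 and CCL20, given as bounds, are uncertain. Among the falls, SELENOP, a selenium transport protein, was 23.5-fold lower, IGSF11 14.3-fold, TMT1A 12.9-fold and MNDA 12.3-fold, while GPD1, LRRC17 and CA10 were at least 14.6-fold, 8.35-fold and 6.09-fold lower, and TNMD fell by 4.39 on the log2 scale. In PBS, IL24 and CXCL3 lay above the control probe sets on 1 of 3 arrays and ITGA2 on 2, and at 24 h TNMD did so on 2 and IGSF11 on 1, so the sizes of these changes are uncertain. Adjusted p-values of these 20 genes were at most 7.91e-05.

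TXNIP itself differed little at 24 h. Its signal was 12370 ± 740 against 10800 ± 178 in PBS (SD, n = 3 each), a log2 fold change of 0.19 ± 0.06 (SE, limma adjusted p = 0.0281). This call rests on 1 of 3 probe sets: the others gave 0.09 and -0.05, neither past the test, and the call was lost on leaving out any PBS array or 24 h replicate 1 or 2 (adjusted p between 0.058 and 0.0839), and under quantile normalization (0.103) or equal array medians (0.0761). Its paralogue ARRDC4 rose 1.16-fold (adjusted p = 0.0101), and ZFP36, which binds AU-rich elements and promotes mRNA decay, rose 1.33-fold (0.0130). The glucose transporter gene SLC2A3 rose 3.54-fold and the hyaluronan receptor gene CD44 2.75-fold (at most 3.17e-06), while SLC2A1 (log2 fold change 0.17, adjusted p = 0.210), the hexokinase gene HK2 (-0.19, 0.394) and HAS3 (0.04, 0.919) did not pass the test. The other HK2 probe sets gave 0.36 and 0.44, the latter past the test at 0.0312, and without PBS replicate 2 the main probe set of HK2 passed as lower (-0.40, adjusted p = 0.0027). SLC2A1 passed as higher without PBS replicate 1 (0.28, adjusted p = 0.0336). HAS3 lay above the control probe sets on 2 of 3 arrays at 24 h.

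**Figure D1:**
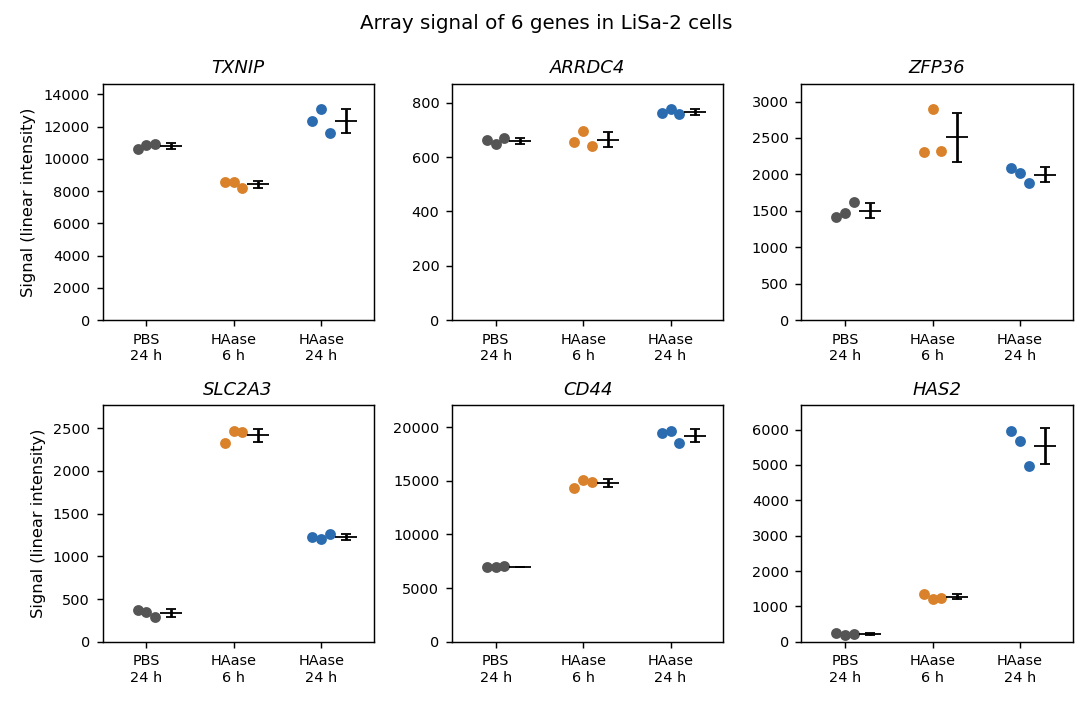
Each panel plots the linear array signal (vertical axis, starting at 0) of 1 gene in the PBS, 6 h and 24 h hyaluronidase groups; points are the 3 arrays of a group, and the bar beside them is the mean with 1 SD. TXNIP lies between 8193 and 8579 at 6 h, below the PBS arrays (10600 to 10930), and HAS2 climbs from 213.2 over 1271 to 5542.

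Of the 35 gene lists, camera called 17 at 24 h, 11 higher and 6 lower. Among inflammatory and NF-kappaB genes, 19 of 28 rose and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 5.96e-12). Of the ERK feedback and output genes 19 of 22 rose and 2 fell (19 and 2 over the list alone; 6.84e-13), including the cyclin gene CCND1 (17.9-fold, from a level above the control probe sets on 2 of 3 PBS arrays) and the phosphatase gene DUSP6 (14.7-fold). Of the AU-rich element mRNAs 21 of 28 rose and 2 fell (22 and 2; 9.62e-13). Immediate early genes rose in 16 of 26 and fell in 4 (17 and 4; 6.23e-06), with IER3 17.3-fold and MAFF 12.8-fold higher. Matrix proteases and crosslinkers rose in 19 of 31 and fell in 6 (19 and 6; 3.43e-06), with ADAMTS6 13.7-fold and the urokinase receptor gene PLAUR 12.1-fold higher. The list of EGF ligands and receptor tyrosine kinases (8 of 17 rose, 3 fell, also over the list alone; 0.0159) included HBEGF (15.6-fold), EREG (at least 5.18-fold), NRG1 (5.73-fold, from a level above the control probe sets on 1 of 3 PBS arrays) and MET (3.05-fold). Its call was lost with an estimated correlation (adjusted p = 0.106).

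The ATF4 and amino acid list had 24 of 30 members higher and 2 lower (24 and 2 adjusted over the list alone; camera adjusted p = 9.62e-13), with the amino acid transporter genes SLC7A5 (6.49-fold) and SLC7A11 (6.28-fold). HIF targets rose in 15 of 23 and fell in 2 (15 and 2; 1.76e-06), with VEGFA 9.57-fold and DDIT4 8.78-fold higher. Metallothionein and metal response genes rose in 8 of 9 (8 over the list alone; 3.01e-07), MT1H by 6.88-fold. Ribosome biogenesis genes rose in 16 of 26 (19 over the list alone; 2.35e-06), with MYC 1.70-fold higher. Of the chaperones and quality control genes of the endoplasmic reticulum 11 of 21 rose and 1 fell (11 and 1; 0.00178), XBP1 by 1.71-fold (another XBP1 probe set gave -0.54, adjusted p = 0.368), and this call was lost with an estimated correlation (adjusted p = 0.0592).

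Adipocyte markers fell in 16 of 21 and 1 rose (16 and 1 adjusted over the list alone; median log2 fold change -1.47, camera adjusted p = 5.61e-07), among them the adipogenic transcription factor gene CEBPA (6.98-fold lower). Fatty acid synthesis genes fell in 13 of 19 and rose in 4 (13 and 4; 0.00174), with the desaturase gene SCD 3.95-fold and LPIN1 3.39-fold lower and the elongase gene ELOVL6 2.72-fold higher. Sterol synthesis genes fell in 13 of 18 and 1 rose (15 and 1; 7.05e-05), with LSS 3.03-fold lower, and the call was lost with an estimated correlation (adjusted p = 0.0592). Respiratory chain genes fell in 32 of 33 by small amounts (33 over the list alone; median -0.44, 1.18e-11), the largest fall being that of UQCRC2 (1.76-fold), and this call too was lost with an estimated correlation (adjusted p = 0.0592). Genes of pyruvate entry and the citric acid cycle fell in 18 of 22 (20 over the list alone; 2.12e-08), led by pyruvate carboxylase (PC, 3.21-fold) and the pyruvate carrier gene MPC1 (2.17-fold). Mitosis genes fell in 21 of 32 and 1 rose (22 and 1; 5.87e-06), with KIF20A 2.07-fold lower. The other 13 calls held with an estimated correlation.

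The remaining lists did not pass camera's test at 24 h, though many of their members changed. Preranked enrichment passed some of them as higher: hyaluronan (adjusted p = 0.00994), leukocyte markers (0.0171), glycolysis (0.0338) and YAP and SRF targets (0.0353). It passed the interferon list as lower (0.0288). Preranked enrichment does not allow for correlation among members, which was estimated at 0.278 for the interferon list. Of camera's 17 calls at 24 h it kept 16 and lost that of the endoplasmic reticulum chaperones (preranked adjusted p = 0.062). For glycolysis 7 of 22 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.115), with the phosphofructokinase regulator genes PFKFB4 (5.22-fold) and PFKFB3 (2.57-fold) higher and ALDOC 2.56-fold lower. Structural matrix genes went both ways (12 of 31 rose, 11 fell, 12 and 13 over the list alone; 0.977): the type I collagen genes COL1A2 and COL1A1 were 4.45-fold and 3.59-fold lower, although another COL1A1 probe set rose (log2 fold change 0.97, adjusted p = 0.0288), and tenascin C (TNC) was 3.47-fold higher. In the hyaluronan list 6 of 21 rose and 2 fell (7 and 2; 0.121), with CEMIP, which takes part in hyaluronan breakdown, 13.6-fold higher. Interferon response genes fell in 15 of 27 and rose in 7 (16 and 7; 0.0989), with MX1 6.93-fold lower (above the control probe sets on 1 of 3 arrays at 24 h) and RSAD2 at least 3.8-fold higher. For the TXNIP and glucose-sensing list 7 of 12 rose and 3 fell (8 and 3; 0.125), and MLXIPL, a glucose-responsive transcription factor gene, was 3.18-fold lower (above the control probe sets on 2 of 3 arrays at 24 h).

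The other lists gave camera adjusted p-values of 0.977 for ZFP36 family and mRNA decay, 0.977 for the pentose phosphate pathway and NADPH, 0.0662 for YAP and SRF targets, 0.134 for TGF-beta targets, 0.913 for cytosolic heat shock, 0.796 for NRF2 targets, 0.913 for p53 targets, 0.796 for FOXO targets, 0.458 for replication and 0.529 for the circadian clock. Markers of other cell types gave 0.977 for epithelial, 0.0590 for leukocyte and 0.397 for endothelial cells. Of the 6 leukocyte markers tested, CD163 (5.44-fold), CSF1R (2.05-fold) and LCP1 (1.85-fold) rose. Of the 7 epithelial markers tested 1 rose and 1 fell, both keratin genes: KRT7 was 1.93-fold higher (adjusted p = 0.00395) and KRT14 at least 5.34-fold lower. The log2 difference between 3' and 5' probe sets, a sign of RNA quality, was lower at 24 h than in PBS by 0.117 for GAPDH and by 0.119 for ACTB (exact permutation p = 0.1, the smallest 3 against 3 can give, and 0.3, two-sided). No sample received inactivated enzyme, so the comparison is of the enzyme preparation with PBS.

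After 6 h of hyaluronidase the largest rises included those of chemokine and cytokine genes and of the immediate early gene EGR1, and TXNIP was lower. CCL20, a chemokine, rose at least 183-fold, to 11900 ± 345 (SD, n = 3) from a level within the range of the control probe sets, and CXCL8 rose 143-fold. EGR1, an immediate early transcription factor, rose 32.4-fold from 388.3 ± 20.5 to 13060 ± 364 (SD, n = 3 each). TXNIP fell from 10800 ± 178 to 8440 ± 214 (SD, n = 3 each), 1.28-fold lower (log2 fold change -0.35 ± 0.06 SE, adjusted p = 0.00169), while its paralogue ARRDC4 gave 0.01 ± 0.05 (0.912). CEBPA fell 8.81-fold and the cell cycle inhibitor gene CDKN1C 8.18-fold.

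This comparison asks which genes differ from PBS after 6 h. The PBS samples were taken at 24 h, so early effects of the enzyme cannot be told apart from the time of harvest. By limma, 5863 of 13842 genes changed (42.4%), 2073 higher and 3790 lower, of which 468 and 446 changed 2-fold or more, and the median of all genes was -0.083. The arrays of the groups did not overlap in 54.2% of the genes, against 10% by chance. The cytokine genes LIF (at least 44.8-fold) and IL6 (26.4-fold), the EGF-family ligand gene EREG (at least 18.0-fold), PTX3 (24.8-fold), INHBA (24.1-fold), DUSP6 (23.8-fold) and GDF15 (23.8-fold) completed the 10 largest rises by the model's fold change. The other large falls were those of the chemokine receptor gene CXCR4 (8.67-fold), TENT5B (8.29-fold), MN1 (7.00-fold), SLITRK5 (6.91-fold), the iron exporter gene SLC40A1 (6.82-fold), RPRM (6.64-fold), SEMA6D (6.52-fold) and IGSF11 (6.08-fold). TENT5B and SLC40A1 lay above the control probe sets on 2 of 3 arrays at 6 h. Another SLC40A1 probe set gave 0.01 (adjusted p = 0.971). Adjusted p-values of the 20 genes were at most 1.85e-05.

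All 3 TXNIP probe sets were lower at 6 h, by log2 fold changes of -0.35, -0.45 and -0.35, the dimmest of them not past the test (adjusted p = 0.173). ZFP36 rose 1.66-fold (adjusted p = 7.89e-04), and its relatives ZFP36L1 and ZFP36L2 were 1.95-fold higher and 1.84-fold lower. SLC2A3 rose 6.90-fold, SLC2A1 1.27-fold (0.0243), CD44 2.11-fold and HAS2 5.64-fold. The SLC2A1 call was lost without PBS replicate 2 or 3 or 6 h replicate 1 or 2 (adjusted p between 0.0567 and 0.0725), and for the mean of its probe sets (0.321). HK2 gave a log2 fold change of 0.43 (adjusted p = 0.061), and its other probe sets gave 0.99 and 0.95, both past the test (0.00645 and 9.08e-04). HK2 also passed without PBS replicate 2 (0.22, adjusted p = 0.0288) or PBS replicate 3 (0.56, 0.0320). The mean of its probe sets passed too (0.79, adjusted p = 7.7e-04). So did its main probe set with the 50th percentile filter (0.0321) or the trended and robust variance model (0.0192). HAS3 gave -0.24 (0.506) and did not pass.

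Camera called 19 lists at 6 h, 15 higher and 4 lower, and 9 of these held with an estimated correlation. Those 9 were inflammatory and NF-kappaB genes (22 of 28 rose, 23 adjusted over the list alone; camera adjusted p = 9.98e-19), ERK feedback and output (20 of 22 rose and 1 fell, as over the list alone; 1.22e-17), AU-rich element mRNAs (20 of 28 rose and 2 fell, as over the list alone; 5.91e-16), immediate early genes (18 of 26 rose and 2 fell, 21 and 2 over the list alone; 4.34e-13), ribosome biogenesis (20 of 26 rose and 1 fell, as over the list alone; 9.56e-10), metallothioneins and metal response (9 of 9 rose; 3.01e-08), matrix proteases and crosslinkers (16 of 31 rose and 3 fell, 17 and 4 over the list alone; 3.37e-06), YAP and SRF targets (12 of 23 rose and 1 fell, 13 and 1; 8.51e-05) and, in the other direction, mitosis genes. Of the mitosis genes 30 of 32 fell (31 over the list alone; median -0.77, 4.08e-13), among them CENPE (4.47-fold), KIF20A (3.57-fold) and CDC20 (2.6-fold). Within the lists that rose, FOS was at least 4.33-fold, MYC 2.55-fold, PLAUR 5.98-fold, the tissue factor gene F3 3.84-fold and MT2A 3.39-fold higher.

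The other 10 calls at 6 h were lost with an estimated correlation. Those higher were EGF ligands and receptors (9 of 17 rose, 3 fell, as adjusted over the list alone; camera adjusted p = 0.00183, with an estimated correlation adjusted p = 0.0587), the ATF4 and amino acid list (15 of 30 rose, 8 fell, 16 and 9 over the list alone; 0.00183, estimated 0.0587), hyaluronan metabolism and binding (8 of 21 rose, 1 fell, 8 and 1; 0.00231, estimated 0.0812), HIF targets (12 of 23 rose, 7 fell, 12 and 8; 0.0072, estimated 0.122), TGF-beta targets (10 of 19 rose, 4 fell, 10 and 5; 0.00796, estimated 0.0587), structural matrix (13 of 31 rose, 6 fell, 13 and 6; 0.0125, estimated 0.281) and glycolysis (7 of 22 rose, 1 fell, 7 and 1; 0.0290, estimated 0.0880). The glycolysis list had a median of 0.006 and a mean of 0.287, with SLC2A3, PFKFB4 (3.11-fold) and PFKFB3 (2.77-fold) higher and 14 members not past the test. Whether its call depends on these 3 genes was not tested. The estimated correlation was negative for glycolysis (-0.015) and TGF-beta targets (-0.022), so correlation among their own members does not account for these lost calls. The lower ones were the citric acid cycle (12 of 22 fell, 13 over the list alone; 0.00229, estimated 0.0639), the respiratory chain (13 of 33 fell, 13 over the list alone; median -0.15, 0.00246, estimated 0.336) and sterol synthesis (12 of 18 fell, 2 rose, 12 and 2; 0.00721, estimated 0.180).

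The lists not called at 6 h included adipocyte markers (10 of 21 fell, 5 rose, 10 and 5 adjusted over the list alone; camera adjusted p = 0.353), where CEBPA, PPARGC1A (5.48-fold) and the lipase gene LIPE (4.51-fold) fell and the lipid droplet gene PLIN2 was 3.10-fold higher, though another PLIN2 probe set gave -0.28 (0.716). Preranked enrichment passed the adipocyte list as lower at 6 h (adjusted p = 0.0112). Of camera's 19 calls at 6 h it kept 16. It lost those of the citric acid cycle (preranked adjusted p = 0.115), the respiratory chain (0.0516) and structural matrix (0.0516). By camera FOXO targets gave 0.475, with PDK4 5.04-fold lower, and the circadian clock list 0.701, with DBP 5.55-fold lower (above the control probe sets on 1 of 3 arrays at 6 h). Fatty acid synthesis gave 0.0973, replication 0.237, p53 targets 0.475, TXNIP and glucose sensing 0.205 (4 of 12 rose, 2 fell), ZFP36 family and mRNA decay 0.755, interferon response 0.621, heat shock 0.932, NRF2 targets 0.255, endoplasmic reticulum chaperones 0.237, the pentose phosphate pathway and NADPH 0.621, and markers of epithelial, leukocyte and endothelial cells 0.850, 0.237 and 0.437. In the TXNIP and glucose-sensing list MLXIPL was 1.67-fold lower at 6 h (adjusted p = 0.0495). This call was lost without PBS replicate 2 or 3, any 6 h array or 24 h replicate 1 (0.0689 to 0.144), and with the mean of probe sets, no filter, quantile normalization or an offset of 1 (0.0555 to 0.082). The ACTB 3' to 5' difference was 0.276 lower at 6 h than in PBS (exact two-sided permutation p = 0.1) and that of GAPDH 0.033 lower (0.3). The 6 h samples were set against PBS samples taken at 24 h, so the length of treatment and the time of harvest differ together in this comparison.

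**Figure D2:**
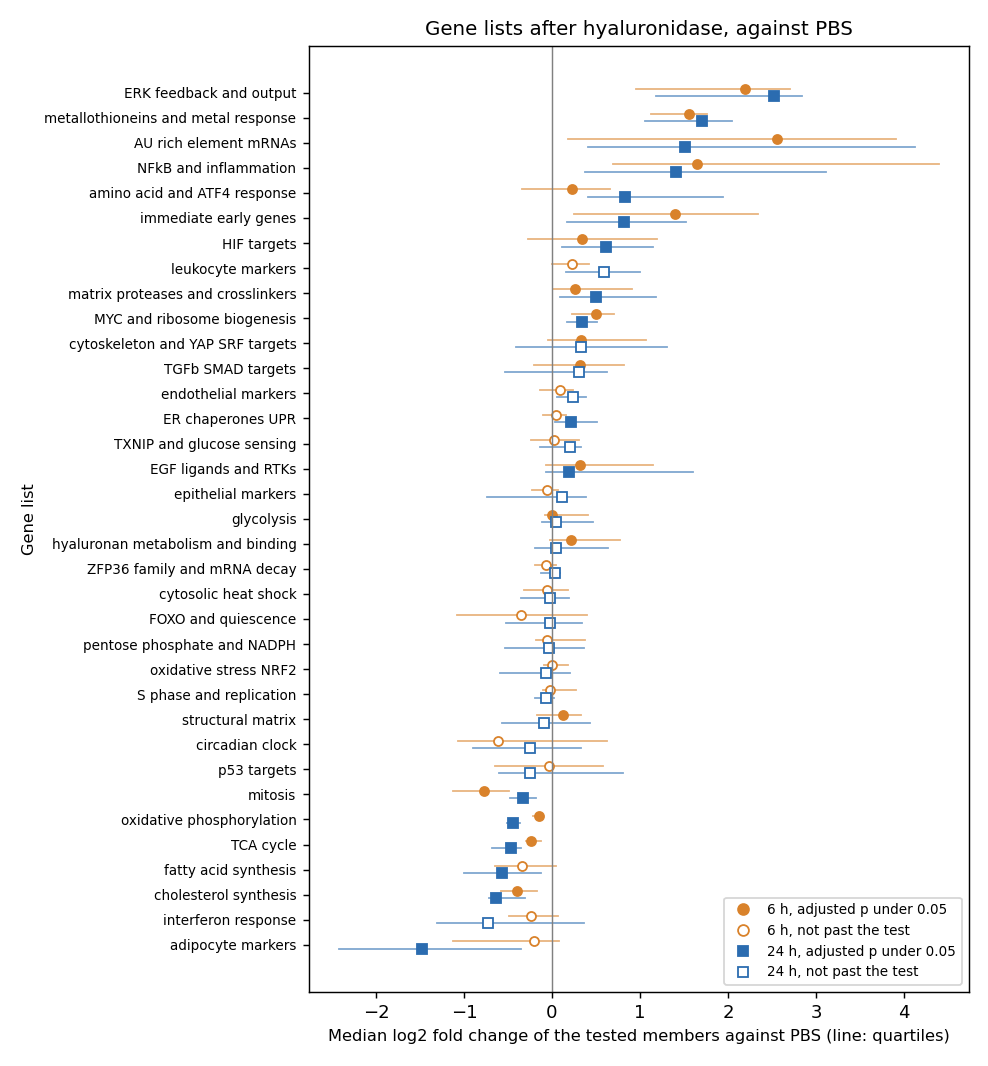
Each row is a gene list, placed by the median log2 fold change of its tested members against PBS (horizontal axis) at 6 h (circles) and 24 h (squares), with a line over the quartiles; filled symbols passed camera's test at an adjusted p under 0.05. ERK feedback genes have the highest median at 24 h and adipocyte markers the lowest, at -1.47, with mitosis genes lower at 6 h (-0.77) than at 24 h (-0.33).

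Between 6 h and 24 h of hyaluronidase, immediate early and inflammatory genes fell, genes of the ATF4 and amino acid list rose, and adipocyte markers fell. CCL20 was 18.4-fold lower at 24 h than at 6 h, and EGR1 fell from 13060 ± 364 to 1159 ± 43.1 (SD, n = 3 each), 11.1-fold. MMP1 was 20.6-fold and HAS2 4.31-fold higher at 24 h than at 6 h. TXNIP was 1.46-fold higher at 24 h than at 6 h (log2 fold change 0.55 ± 0.06 SE, adjusted p = 2.69e-04). Its other probe sets gave 0.40, past the test, and 0.44, not past it (limma adjusted p = 0.11).

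This comparison asks which early changes last, and the length of treatment and the time of harvest differ together in it. By limma, 4567 of 13842 genes differed (33.0%), 2731 higher at 24 h and 1836 lower, of which 237 and 321 differed 2-fold or more. DNER (13.5-fold), ITGA2 (8.49-fold), KRT33A (7.95-fold) and the elastase inhibitor gene PI3 (7.03-fold) followed MMP1 among the rises, and BBOX1 (12.7-fold), TNMD (11.6-fold) and SELENOP (10.8-fold) were among the falls. KRT33A lay above the control probe sets on 1 of 3 arrays at 6 h, and TNMD on 2 of 3 at 24 h. ARRDC4 was 1.15-fold and CD44 1.30-fold higher at 24 h, while SLC2A3 (1.95-fold), HK2 (1.54-fold) and ZFP36 (1.25-fold) were lower (adjusted p at most 0.0441). The ZFP36 call was lost without any 1 of 8 arrays, all but 6 h replicate 1 (adjusted p between 0.0502 and 0.123). It was also lost with no filter (0.0777), the 6 arrays alone (0.0784), the mean of probe sets (0.0593) or every probe set tested (0.0597). The HK2 call was lost without 6 h replicate 2 or 24 h replicate 2 or 3 (0.0534 to 0.0578). Another HK2 probe set gave -0.63 and did not pass (0.0535). The ARRDC4 call was lost without 6 h replicate 3 (0.0539). Of the 9 other CD44 probe sets above the filter, 6 rose past the test, by log2 fold changes of 0.63 to 0.92, and 3 did not pass (-0.42, -0.14 and 0.06). SLC2A1 (log2 fold change -0.17, adjusted p = 0.230) and HAS3 (0.28, 0.461, above the control probe sets on 2 of 3 arrays at 24 h) did not pass the test.

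Camera called 17 lists between the times, 4 higher at 24 h and 13 lower, and 6 held with an estimated correlation. Preranked enrichment kept 10 of the 17 in the same direction. Mitosis genes were higher at 24 h than at 6 h (29 of 32, also adjusted over the list alone; camera adjusted p = 1.95e-10), as was the ATF4 and amino acid list (26 of 30 rose and 2 fell, as over the list alone; 5.12e-10), where ASNS, the asparagine synthetase gene, was 6.99-fold and SLC7A5 3.99-fold higher. Lower were adipocyte markers (15 of 21 fell and 1 rose, 16 and 1 over the list alone; 5.12e-10), immediate early genes (18 of 26 fell, 18 over the list alone; 3.31e-07), the citric acid cycle (15 of 22 fell, 1 rose, 15 and 1; 3.69e-07) and inflammatory genes (17 of 28 fell, 6 rose, 17 and 6; 3.1e-05), although CCL5 was 6.17-fold higher. The respiratory chain (27 of 33 fell, 29 over the list alone; 1.57e-11) and structural matrix (13 of 31 fell, 4 rose, 15 and 6; 9.43e-04) were lower too, with adjusted p = 0.0927 and 0.182 with an estimated correlation. COL3A1 was 2.50-fold and THBS1 3.11-fold lower at 24 h than at 6 h.

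The other 9 calls between the times were lost with an estimated correlation, at adjusted p between 0.0882 and 0.485. HIF targets and endoplasmic reticulum chaperones were higher at 24 h, and ribosome biogenesis, replication, fatty acid synthesis, sterol synthesis, interferon response, TGF-beta targets and p53 targets were lower. The interferon call was lost without 6 h replicate 1 (camera adjusted p = 0.0624), and the p53 call without PBS replicate 2, 6 h replicate 3 or 24 h replicate 2 (0.0561 to 0.0772). The median, mean and test of a list differed in sign in 5 lists at 24 h, 5 at 6 h and 6 between the times, and camera called 0 of these.

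Many genes changed at both times. Of 13842 genes, 3529 changed in the same direction against PBS at 6 h and 24 h, 1415 higher and 2114 lower, against 363 and 864 for independent lists of these sizes. Both comparisons use the same PBS arrays. In 100 simulations of unchanged groups against shared controls the mean was 0.03 genes. With no gene changed the test calls almost none, so this count does not measure what shared controls add to the 3529. The simulated correlation of log2 fold changes across genes was 0.5, against 0.726 observed. The simulated covariance was 0.0155, against 0.279 observed. With 3 PBS arrays the controls could not be split into parts of 2 arrays each, and part of the excess may come from the shared controls. In 230 genes the directions were opposite, 113 higher at 6 h and lower at 24 h and 117 the reverse. The 6 h arrays also differ from the PBS arrays in time of harvest.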

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

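The comparisons, the other scalings and the estimated correlation were planned, and the test of the brightness of the respiratory chain probe sets was set before its result was seen. The tests of TXNIP against the median of all genes and against ARRDC4 and MLXIPL, of the replication list and of the splits of the arrays were chosen only after the result was seen, as was the use of the planned scalings to weigh explanations.

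The level after 24 h of hyaluronidase differed from that after 6 h in 4567 genes by limma, and 17 gene lists differed between the times by camera. Both effects were measured against the same 24 h PBS arrays, so these tests compare the levels of the treated groups, in which length of treatment and time of harvest change together. In 113 genes the signal was higher than in PBS at 6 h and lower at 24 h, and in 117 genes the reverse, with each difference past the test. Of the 37 genes named for the largest changes against PBS, 35 differed between the times, against 33.0% of all tested genes. These genes were picked on the same arrays as the extremes at 6 h or at 24 h, which favours such a difference. Among the genes of the study's question, the log2 difference of 24 h minus 6 h was 0.55 for TXNIP, 0.20 for ARRDC4, -0.32 for ZFP36, -0.97 for SLC2A3, -0.63 for HK2, 0.38 for CD44 and 2.11 for HAS2.

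A signal also appeared in probe sets outside the gene comparisons. Of 5949 tested probe sets with no gene symbol or with several, 951 differed from PBS at 24 h and 1052 at 6 h by limma.

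TXNIP was lower than PBS at 6 h and not at 24 h. Array scaling does not account for the 6 h value: TXNIP minus the median of all genes was -0.272, and TXNIP was lower past the test under quantile normalization and equal array medians too. Less glucose-responsive transcription stays open: ARRDC4, which responds to glucose through a like promoter element, gave 0.008 at 6 h, with -0.09 at 2 SE below it against -0.241 at 2 SE above the TXNIP estimate, but this is 1 gene. MLXIPL, a glucose-responsive transcription factor gene, does not decide it either: it was lower at 6 h (-0.74, adjusted p = 0.0495), a call lost under several alternatives (0.0555 to 0.144), and lower still at 24 h (-1.67), where TXNIP gave 0.194 and ARRDC4 0.21. Time of harvest and treatment cannot be told apart at 6 h, because the PBS arrays are all from 24 h.

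Mitosis genes were lower at 6 h, with a median of -0.772. A smaller share of cycling cells could lower replication genes too. The median of the replication list was -0.02, with a 95% bootstrap interval over genes from -0.078 to 0.103, above -0.386, which is 0.5 of the mitosis median. Genes of a list are not independent replicates, so this interval describes these lists only. Replication genes thus did not fall as a set as mitosis genes did. Their members went both ways (9 of 30 rose, 5 fell), so rises could mask falls, and this cannot decide whether fewer cells were cycling. Time of harvest and treatment cannot be told apart at 6 h for want of a 6 h PBS group, and the list's median at the matched 24 h was -0.33.

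Respiratory chain genes were lower at 24 h. The brightness of the probe sets does not account for it, since 0% of 10000 random lists matched on mean expression had a median as low, the lowest being -0.181. Array scaling does not either, since the median was -0.465 under quantile normalization and -0.444 with equal array medians. The list's call was lost with an estimated correlation (adjusted p = 0.0592), and no biological cause of the lower level was tested.

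For each comparison the 6 arrays make 10 splits into 3 and 3, which are too few for a share under 0.05, and the real split was the 1 with the most calls each time. The real splits gave 5577, 5863 and 4567 genes at 24 h, at 6 h and between the times, and the highest other split gave 0 genes each time. The real splits gave 17, 19 and 17 gene lists, and the highest other splits gave 15, 14 and 10. Every other split put arrays of both groups in each part. The group difference then widened the spread within the parts, and some of it stayed in the contrast. The other splits therefore give no chance level, for genes or for lists.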

How the results depend on the processing

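Every alternative was planned, and none was added after the data were examined. The counts of changed genes stayed within 1.5 times in 58 of 60 recomputations, with ranges from 4499 to 8857 at 24 h, 4582 to 8884 at 6 h and 3238 to 6624 between the times; the exceptions were 8857 genes at 24 h and 8884 at 6 h with every probe set tested, where 26599 probe sets entered in place of genes. Leaving out each array gave 4818 to 5443, 4903 to 5806 and 3718 to 4399 genes. The genes changed in the same direction at both times numbered 2690 to 3869 (2903 to 3291 leaving out arrays). The counts of lists stayed within 1.5 times in 60 of 66 recomputations; fry, which does not compare a list with other genes, called 31 at 24 h, 30 at 6 h and 28 between the times, camera with an estimated correlation called 9 at 6 h and 6 between the times, and preranked enrichment called 11 between the times. In 7836 recomputations of 396 results for named genes past the test, 7592 kept direction and call, 217 kept only direction and 27 reversed. In 1166 recomputations of 53 list results past the test, 1116 kept both, 50 kept only direction and 0 reversed. In 193 recomputations of 10 gene results not past the test, 9 passed in the same direction and 11 reversed. In 1144 recomputations of 52 list results not past it, 57 passed in the same direction and 44 reversed. Many of these genes were named for large changes, and the alternatives reuse most of the arrays, so a high share kept was likely. Dim signals near the control probe sets limit what can be read from low genes.

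The labels give the groups the same replicate numbers, but residuals of same-numbered arrays correlated between -0.049 and 0.037, with 0 of 9 pairs over 0.1 and the own number correlating best in 3 of 9. No shared effect of the replicate number was thus seen. The labels do not say whether same-numbered samples were handled together. With the replicate number as a block (replicate block) 5187, 5447 and 4117 genes were called at 24 h, at 6 h and between the times, of which 5006, 5268 and 3940 were also called without it. TXNIP gave 0.194 at 24 h and -0.355 at 6 h with the block. The block ended the call of ZFP36 between the times (adjusted p = 0.0758, over all alternatives 0.0102 to 0.123), the calls of 6 other named genes and that of the p53 list between the times (0.0502 to 0.0737), and the leukocyte list passed at 24 h (0.0452).

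The TXNIP value at 24 h lost its call with the mean of its probe sets (0.079), another probe set (0.093), no filter (0.194), quantile normalization (0.124), equal array medians (0.186) and the 6 arrays alone (0.194), and was reversed at -0.049 with the other probe set; over all alternatives its adjusted p ran from 0.00379 to 0.731, and leaving out arrays gave 0.151 to 0.238, with lost calls from 0.151 to 0.202 (without any PBS array or 24 h replicate 1 or 2). TXNIP at 6 h lost its call with 1 other probe set (-0.348), with adjusted p from 3.41e-05 to 0.173. The cause was not tested.

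With another probe set, directions turned at 24 h for HK2 (0.357 and 0.441), COL1A1 (0.974), XBP1 (-0.538), E2F1 (0.162) and DBP (0.05). At 6 h they turned for SLC40A1 (0.014), MLX (-0.035), ERN1 (-0.004 and -0.161), XBP1 (-0.709), HSPH1 (-0.115), PLK3 (-0.044), ACACB (0.236), PLIN2 (-0.284) and CDT1 (-0.081). Between the times they turned for CD44 (-0.423 and -0.143), PGD (0.655), ETV5 (-0.032), MET (-0.116), COL1A2 (0.743), COL1A1 (0.403), FBXO32 (-0.727), LSS (0.316), RFC3 (0.125) and FLT1 (-0.294). Of these turned probe sets, only 1 of HK2 (0.441, limma adjusted p = 0.0312) and that of COL1A1 (0.0288) at 24 h passed the test, and those of FBXO32 (1.66e-04) and LSS (0.0247) between the times. With the mean of all probe sets, directions turned for HK2 at 24 h (0.203), XBP1 at 6 h (-0.217) and PGD between the times (0.009). Leaving out arrays turned HAS3 at 24 h (-0.265 to -0.057, over all arrays -0.265 to 0.24), ARRDC4 at 6 h (-0.025 to -0.005, over all arrays up to 0.031), and between the times HAS3 (-0.025, up to 0.48), FLT1 (-0.158, up to 0.569) and ROBO4 (-0.164, up to 0.552), none of them past the test. The cause was not tested.

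Lists not past the test turned direction, given here as adjusted p, at 24 h for TXNIP and glucose sensing (0.712, preranked enrichment), ZFP36 family (0.946 with no filter, 0.0708 by fry, 0.989 by preranked enrichment, 0.902 to 0.981 leaving out arrays, over all arrays from 0.87), pentose phosphate (0.946 with no filter, 0.923 with quantile normalization, 0.977 with the 6 arrays, 0.574 by preranked enrichment, 0.961 to 0.983 leaving out arrays, over all arrays from 0.902), structural matrix (0.581 with the mean of probe sets, 0.969 with the 50th percentile filter, 0.87 to 0.985 leaving out arrays), heat shock (0.986 with the 50th percentile filter), p53 targets (8.19e-04 by fry, 0.321 by preranked enrichment) and epithelial markers (0.275 with the 50th percentile filter, 0.968 with an offset of 1, 0.918 with the replicate block, 0.872 with the 6 arrays, 0.902 to 0.961 leaving out arrays, over all arrays from 0.876). At 6 h they did so for heat shock (0.656 with the 50th percentile filter, 0.983 with the 6 arrays, 0.893 to 0.987 leaving out arrays, over all arrays from 0.768), the clock (0.705 with the 50th percentile filter) and epithelial markers (0.851 with no filter, 0.996 with the 6 arrays, 0.475 by fry, 0.279 by preranked enrichment, 0.967 leaving out PBS replicate 2, over all arrays 0.639 to 0.987). Between the times they did so for pentose phosphate (0.879, mean of probe sets), hyaluronan (0.709 with the mean of probe sets, 0.00745 by fry, 0.265 by preranked enrichment) and epithelial markers (0.378, 50th percentile filter). The cause was not tested.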

Other observations

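The genes and families named here were chosen only after their values were seen, and the tests on families were added then too.

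Among the genes that changed in opposite directions at the times, the actin-binding gene LIMA1 was higher than PBS at 6 h (log2 fold change 1.20 ± 0.06, SE) and lower at 24 h (-1.22 ± 0.06). The adipogenic transcription factor gene CEBPD went from 1.11 to -0.99, whereas CEBPA was lower at both times. The integrin gene ITGB8 went from 1.88 to -0.94, the guanylate-binding protein gene GBP1 from 1.06 to -0.89 and the cadherin gene CDH11 from 1.29 to -0.86. In the other direction, PSAT1, an enzyme gene of serine synthesis, was lower at 6 h (-0.83 ± 0.05) and higher at 24 h (0.95 ± 0.05), and the lipoprotein receptor gene VLDLR went from -1.35 to 0.58. All of these passed limma's test at each time. The 6 h values are against PBS taken at 24 h, so treatment and time of harvest differ together in them.

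Genes were also grouped by the stem of their symbols into 167 families of at least 10 tested genes, and camera was run on these. Camera called 6 families at 24 h, 5 at 6 h and 3 between the times, and 0 of these calls held with an estimated correlation. That test is stricter for every family, since it rests on the few arrays and is adjusted over all 167. The lost calls therefore do not show that members of a family vary together. At 6 h, IL genes, among them interleukins and their receptors, rose in 20 of 51 and fell in 2 (camera adjusted p = 5.38e-05, with an estimated correlation adjusted p = 0.346), and UTP genes of ribosomal RNA processing rose in 10 of 10 (3.46e-04, estimated 0.480). Centrosomal protein genes of the CEP family fell in 22 of 36 (0.00131, estimated 0.5). Genes with CD symbols rose in 14 of 53 and fell in 5 (0.0171, estimated 0.480), and collagen genes (COL) rose in 10 of 28 and fell in 3 (0.0297, estimated 0.480). At 24 h, NDUFA and NDUFB genes of respiratory complex I fell in 11 of 12 (0.00245) and in 10 of 12 (0.00598), and COX genes fell in 16 of 28 (0.00781). At that time IL genes rose in 22 of 51 and fell in 5 (0.00392), UTP genes rose in 7 of 10 (0.0114) and CHST sulfotransferase genes rose in 5 of 12 and 1 fell (0.0155). The adjusted p of each of these 6 families was 0.669 with an estimated correlation. Between the times NDUFA fell in 8 of 12 (0.00215), NDUFB in 7 of 12 (0.00521) and COX in 10 of 28, with 1 higher (0.0276). For each of these 3 the adjusted p was 0.85 with an estimated correlation.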
